A study of Mus musculus with 3 samples.

How the data were processed

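Gene expression was measured in 3 RNA samples of mouse C3H10T1/2 cells, 1 untreated and 1 each after Cr(VI) at 1 uM and 0.01 uM, on 3 arrays of 1 slide. Because slide and scan were shared, no batch could be separated. Spot intensity was extracted by the authors with Agilent Feature Extraction 10.5.1.1 from a single-channel Cy3 scan, per the file headers, which record spatial and multiplicative detrending and surrogate values for spots not above background. The deposited value table of the series holds log2 values whose making is not given in the sources used here. Set against the scanner values, each of its columns differed from log2 processed signal by 1 constant (9.45 for untreated, 9.01 for 0.01 uM and 9.56 for 1 uM), within 0.01 for over 99.8% of 41167 probes. The column medians were -4.23, -3.96 and -4.03. Its scale, centring and direction are therefore those of the main setting.

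Outlier-flagged spots and control spots were left out and spots of a probe were averaged on the log2 scale. Each array's 75th percentile over all probes was subtracted. That rule was fixed before the data were examined. Since under 50% of the probes were well above background, the 75th percentile of probes detected on all arrays was added as an alternative. A gene was represented by its brightest probe over the 3 arrays. Probes were named through RefSeq accessions (25097 probes), the file's symbol (6333) or a synonym (1640), and 8104 kept the file's own name. The RefSeq table is of assembly GRCm38.p6 and was used for names only. Coordinates are those of the array files, build mm9.

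A gene was compared where its probe was well above background on at least 1 of the 2 arrays. Where 1 array was not, the fold is a lower bound, the brighter value against the higher of the dim value and the lowest signal among detected probes of that array. A saturated brighter spot also gives a bound, and genes saturated on both arrays were given no fold and counted as not apart. With 1 array per group no p-value was computed. Genes at least 2-fold apart were counted, and list medians of measured values were ranked among 10000 random lists of the same size matched on brightness in 20 bins. The 36 lists in 3 comparisons made 108 such ranks. Log2 differences are dose minus untreated, or 1 uM minus 0.01 uM.

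Named genes were the 12 with the largest difference per direction (6 for 1 uM against 0.01 uM) among official symbols at least 2-fold apart in the same direction with 75th-percentile, normexp and quantile settings, with a brighter signal at or above the 25th percentile of detected probes. Up to 4 members per list and direction were added, with members of both ERK lists, and the 2 brightest members of lists with none past 2-fold. Some genes that met the rule are not reported here. A further probe at least 1.5-fold the other way was to be named. Of 292 genes past 2-fold with several probes at 1 uM, 10 had one, and 55 had another probe within 1.5-fold.

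Alternatives were the median of detected probes, quantile normalization, normexp (limma 3.58.1 in R 4.3.3, offset 50), a filter on both arrays, no filter, the mean of probes, outlier spots kept, the authors' value table and a 3-fold threshold. Loess scaling (span 0.4) and scaling on 6 unsaturated spike-in controls were added after seeing the data. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6. The counting was tested on simulated data with a noise SD of 0.14 per array. For 1 uM against untreated, run on 11869 genes, 0 of 50 genes changed 1.5-fold, 20 of 49 changed 2-fold, 48 of 50 changed 3-fold and 48 of 50 changed 4-fold were counted, with 0 of 11670 unchanged genes. The simulated genes were drawn from those detected on the reference array, with even noise and no saturation. Small noise fixed the last count in advance, so it says nothing about false counts in the real arrays. Lists of 25 genes shifted by 0.5 passed percentile 99 in 20 of 20 cases, and 2 of 100 unshifted lists lay outside percentiles 1 to 99. The number of arrays limits the precision of every value.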

Results

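The series asked how gene expression differed in mouse C3H10T1/2 cells, an embryonic fibroblast-like line used in cell transformation assays, after exposure to hexavalent chromium, Cr(VI). One culture group was left untreated, 1 received Cr(VI) at 1 uM and 1 at 0.01 uM. Exposure lasted 48 h, began 24 h after 2000 cells were seeded per flask, and the cells were kept to day 15. If the RNA was taken on day 15, the arrays describe cells days after exposure had ended, not cells under the dose. Each group had 3 flasks and 1 array, so there were no replicates. The labels do not say whether the RNA of the 3 flasks was pooled. No test between conditions was possible, and every value below is a difference between 2 single arrays. The series title names ERK activation, gene dysregulation and cell transformation as the subject.

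RNA was labelled with Cy3 and hybridised to Agilent whole-genome mouse arrays with 41167 usable probes. The share of probes well above background was 41.8% on the untreated array, 36.4% on the 0.01 uM array and 41.5% on the 1 uM array. The median SD of log2 signal between replicate spots of a probe was 0.058, 0.057 and 0.062 in the same order. The scanner software's own error model put the median standard error of a log2 difference at 0.21 for 1 uM against untreated. These errors are technical and leave out differences between cultures.

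The first comparison asked which transcripts differed after 1 uM Cr(VI). Relative to the 75th percentile, the median of interferon response genes was higher on the 1 uM array, and those of fibrillar matrix and smooth muscle genes were lower. Saa3, an acute-phase serum amyloid gene, was 40.5-fold higher, and Akr1c18, a steroid-metabolising reductase, was 16.6-fold higher. Thy1, a fibroblast surface glycoprotein, was at least 50.2-fold lower, and Islr was 21.5-fold lower. The immediate early genes Fos and Fosb were lower by 14.0-fold and 19.6-fold. Of 12450 genes compared, 693 were at least 2-fold higher and 605 at least 2-fold lower. The share of higher genes was 53.4%. It was 63.5% after loess scaling (912 higher, 524 lower) and 95.5% after spike-in scaling (3520 higher, 165 lower), both chosen after seeing the data. Spike-in scaling put the median of all detected genes at 0.69, and the differences given here are relative to the 75th percentile instead. The amounts of spike-in and RNA per labelling are not known, so that scaling does not give RNA per cell. It raises every list median by the same amount within a comparison, and turns those that lie little below 0. With normexp background correction the counts were 290 higher and 450 lower.

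**Figure D1:**
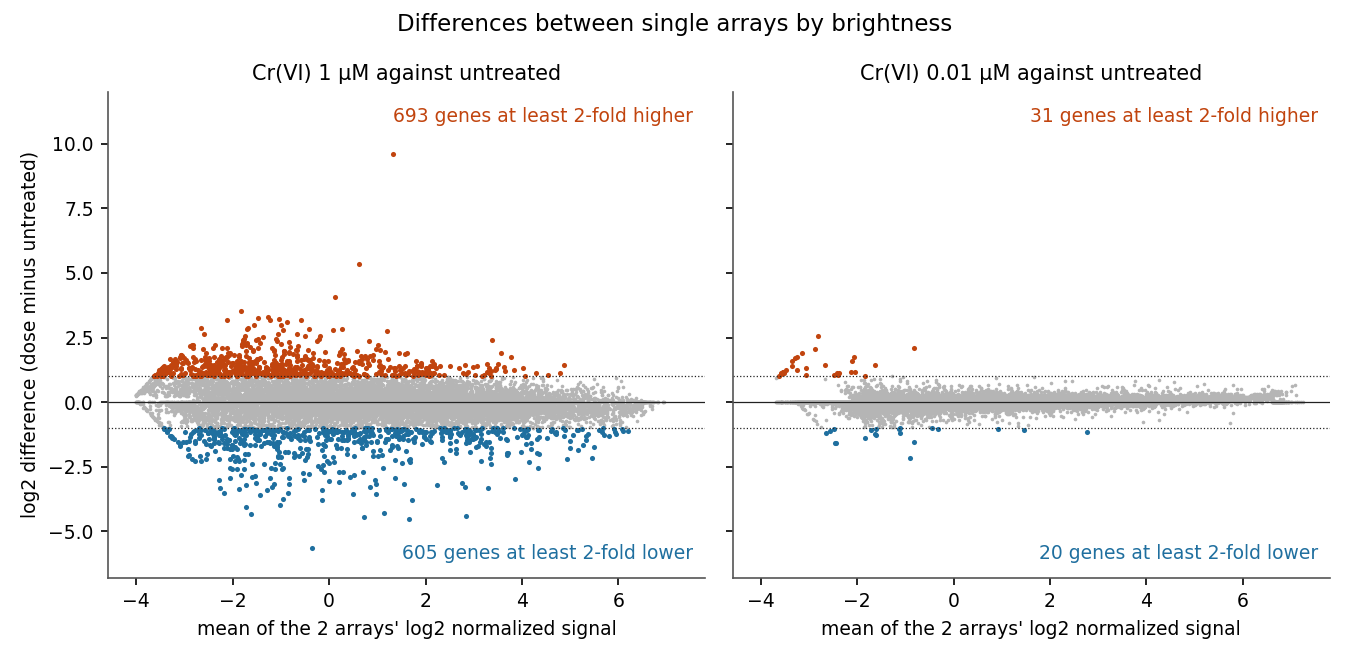
Log2 difference between a dose and the untreated array (vertical axis) against the mean log2 normalized signal of the 2 arrays (horizontal axis), with 1 point per gene and dotted lines at 2-fold. The left panel holds 693 higher and 605 lower genes at 1 uM, and the right panel 31 and 20 at 0.01 uM.

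Among the genes with the largest differences, Msln, a surface protein, was 8.56-fold higher and Plcg2, a phospholipase of immune signalling, 7.85-fold higher at 1 uM. Ces2e, a carboxylesterase, was 8.95-fold higher. Cd74, the MHC class II invariant chain, was at least 9.83-fold higher, Ptprv at least 9.61-fold and Rnase2a at least 9.33-fold, since none of these was well above background on the untreated array. Another Ptprv probe was at 2.45 on the log2 scale, below that bound. On the lower side stood Ccn5 (22.9-fold), Sema3g (22.0-fold), Galnt15 (13.9-fold), Rarres2 (at least 13.4-fold) and Colec10 (at least 12.2-fold). Another Rarres2 probe was at -2.91 on the log2 scale, nearer 0 than that bound. The bound for Mfap5, a microfibril protein, was -4.32 on the log2 scale. Adat1 had the highest value, at least 767-fold higher, but it rested on 1 saturated spot. The other 2 Adat1 probes differed by 0.49 and 0.03 on the log2 scale, so its level is uncertain. The Thy1 probe lies on chromosome 9 from 43856600 to 43856659, the Saa3 probe on chromosome 7 from 53968031 to 53968090 and the Fos probe on chromosome 12 from 86817900 to 86817959 (mm9 coordinates of the array files).

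**Figure D2:**
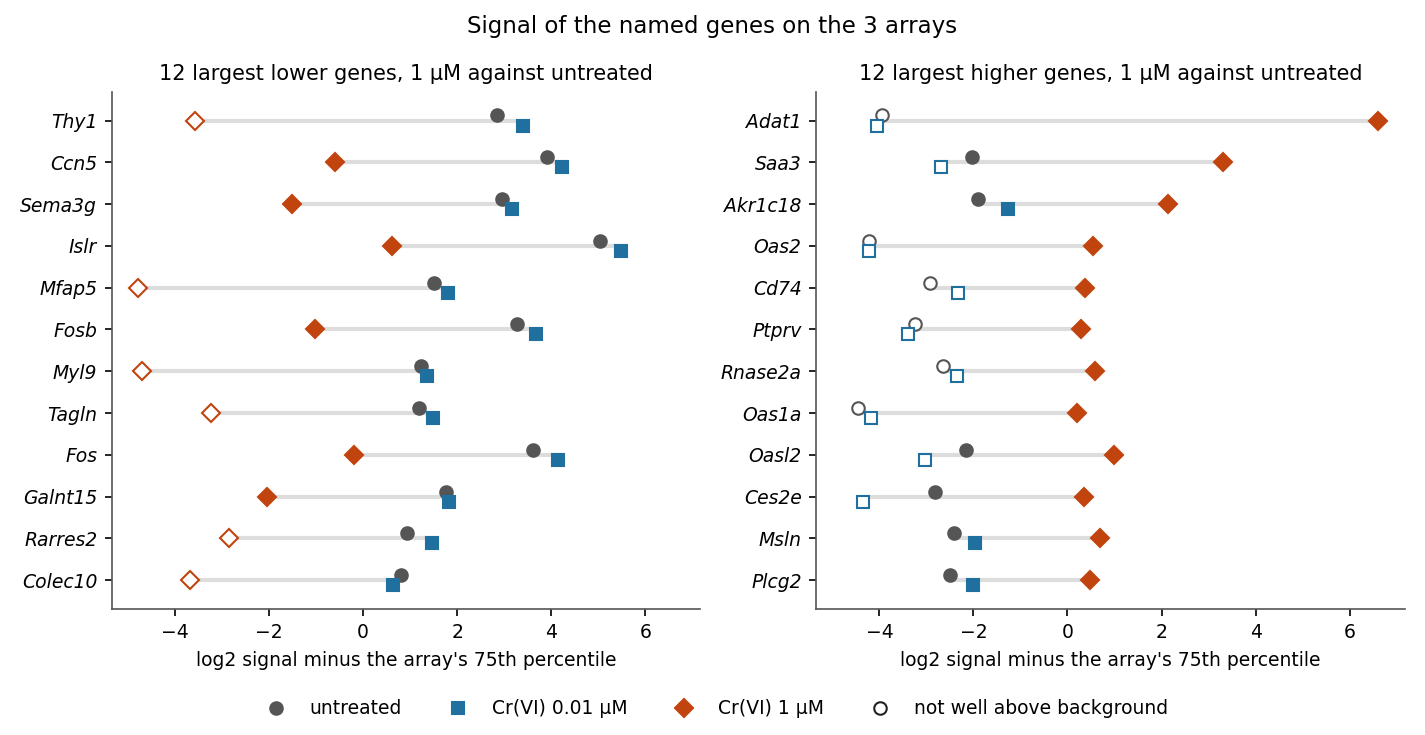
Log2 signal minus the array's 75th percentile (horizontal axis) on the untreated, 0.01 uM and 1 uM arrays, for the 12 genes with the largest difference in each direction between 1 uM and untreated. Open symbols were not well above background. Thy1 stands at 2.84 on the untreated and -3.56 on the 1 uM array.

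Interferon response genes had the highest median of the 36 lists fixed before the data were examined. Their median log2 difference at 1 uM was 1.33, at percentile 100 of 10000 random lists of equal size and brightness. Of 33 measured members, 19 were at least 2-fold higher and 0 at least 2-fold lower. Oasl2 was 8.97-fold higher, Oas2 at least 11.6-fold, Oas1a at least 9.15-fold and Zbp1 at least 7.33-fold. The first 3 encode oligoadenylate synthetases or a related protein, and Zbp1 encodes a nucleic acid sensor. Oas and Oasl genes have close relatives, so the split among copies is uncertain. Among 11 measured antigen presentation genes, Cd74 was the 1 gene at least 2-fold apart. Of 31 measured chemokine and inflammatory genes, 5 were at least 2-fold higher and 2 lower, with a median of 0.21, which was 0.032 with both arrays required to be well above background. Ccl3 was at least 5.47-fold higher, Il33 3.70-fold and Ccl8 2.68-fold, whereas Cxcl12, a stromal chemokine, was at least 4.49-fold lower and the interleukin 1 antagonist Il1rn 9.19-fold lower. Of 22 macrophage and blood cell markers, 3 were well above background on the untreated and 4 on the 1 uM array.

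Immediate early genes, the transcription factors and feedback regulators induced within minutes of a stimulus, had a median of -0.95 at 1 uM. Of 20 measured members, 10 were at least 2-fold lower and 1 was higher. Egr3 was 11.4-fold lower and Klf2 5.90-fold lower, with another Klf2 probe at -1.33 on the log2 scale. Nr4a2 was the exception, at 2.81-fold higher. YAP and SRF target genes had 4 of 20 members at least 2-fold lower and 0 higher, among them Ccn2 (3.62-fold) and F3 (2.95-fold). The median of the YAP and SRF list was -0.30, at percentile 2.76 of the random lists, and 0.44 after spike-in scaling.

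Matrix and contractile lists had medians below 0 at 1 uM, which spike-in scaling turned to 0.19 for collagens and fibrillar matrix and 0.24 for smooth muscle and TGF-beta response genes. Of 36 measured collagen and fibrillar matrix genes, 8 were at least 2-fold lower and 2 higher, with a median of -0.55. Fbln1 was 9.11-fold lower and Fbln5 4.98-fold, whereas Tnc, a matrix glycoprotein, was 3.05-fold higher and Col8a1 2.66-fold. Of 26 smooth muscle and TGF-beta response genes, 8 were lower and 1, Tgfbr1, was higher, with a median of -0.50. The actin-associated genes Tagln and Myl9 were at least 16.0-fold and 16.5-fold lower, although another Tagln probe was at -2.64 on the log2 scale, nearer 0 than that bound. Bone and cartilage genes went both ways. Of 14 measured, 6 were at least 2-fold lower, including Comp (at least 6.08-fold) and the cartilage collagen Col2a1 (-3.17 on the log2 scale). The other side held 3 genes, Bglap (5.88-fold), Dmp1 (5.15-fold) and Phex (2.51-fold), which belong to mineralised tissue. The median of that list was -1.23, or -0.35 with bounds in place of dim values, and was 0.15 when probes below background on both arrays were let in. Among matrix proteases and inhibitors, Mmp3 and Mmp13 were 7.15-fold and 5.38-fold higher. On the other side, Adamts5 was 2.04-fold lower.

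**Figure D3:**
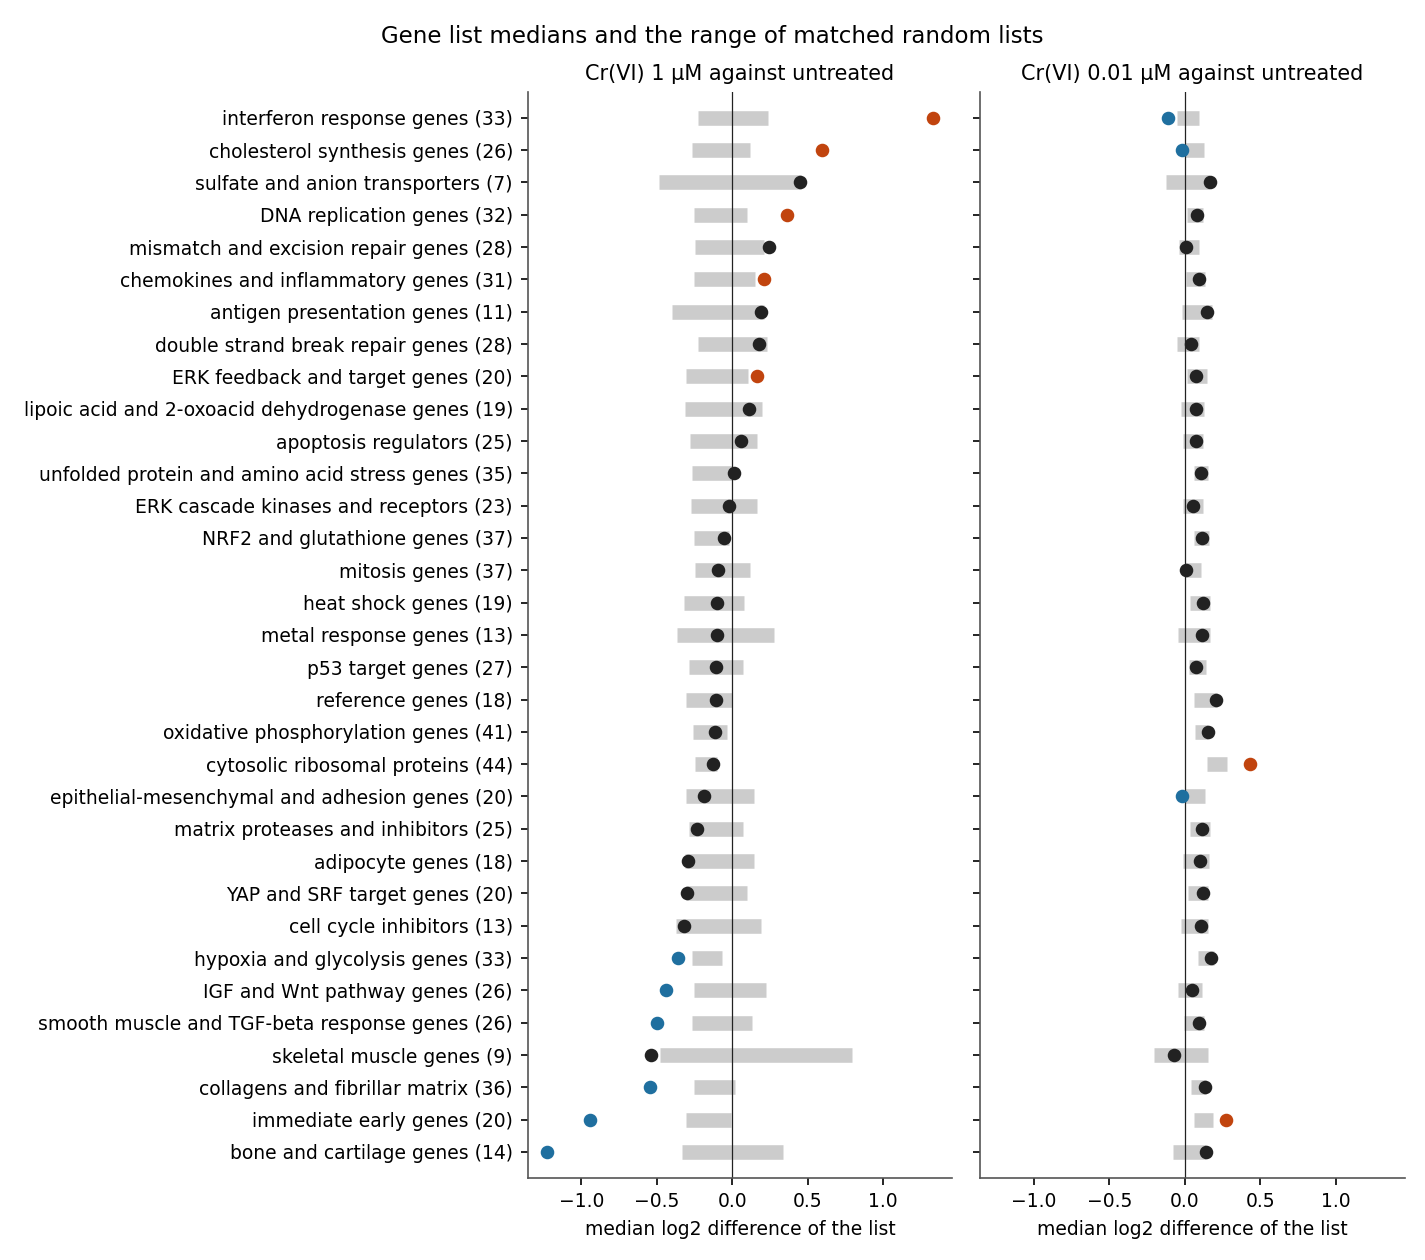
Median log2 difference of each fixed list (dots, horizontal axis, lists with at least 7 measured genes, number in brackets) with the central 95% range of 10000 matched random lists (grey bars). Orange dots lie above percentile 99 and blue dots below percentile 1. Interferon response genes reach 1.33 at 1 uM, and no list median at 0.01 uM exceeds 0.44.

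Some growth factor, lipid and metabolic genes were 2-fold apart at 1 uM. Of 26 IGF and Wnt pathway genes, 7 were at least 2-fold lower and 3 higher, with a median of -0.44, or -0.13 without a filter on dim probes and 0.29 after spike-in scaling. The growth factor Igf2 was 11.9-fold lower (-4.42 on the log2 scale with another probe), Sfrp2 at least 7.11-fold and Igfbp2 4.26-fold, whereas the Wnt inhibitor Dkk2 was 3.78-fold higher. All 7 cholesterol synthesis genes past 2-fold, of 26, were higher, with a list median of 0.60. Hmgcs1, the HMG-CoA synthase gene, was 2.53-fold higher, and Idi1 was 1.32 higher on the log2 scale. Of 33 hypoxia and glycolysis genes, 4 were lower and 1 higher, with a median of -0.36, or -0.14 after quantile normalization and 0.37 after spike-in scaling. Pfkfb3 was 4.15-fold lower and the lactate transporter Slc16a3 2.68-fold. Of 18 adipocyte genes, 3 were lower, including Fabp4 (5.26-fold), and 0 were higher.

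DNA replication genes had a median of 0.37 over 32 members. Of these, 1 gene, Ccne1, was at least 2-fold higher (2.25-fold) and 7 at least 1.5-fold. Of 37 mitosis genes, 1 was at least 2-fold lower (Cdc25c, 2.09-fold). Among p53 target genes, 1 of 27 was higher and 1 lower, the latter being Btg2 (3.96-fold, with other probes at -1.23 and -0.97 on the log2 scale). Of 28 mismatch and excision repair genes, the alkyltransferase gene Mgmt was the 1 gene past 2-fold, at least 2.61-fold lower. Its signal was well above background on the untreated array only (-1.42), and not at 0.01 uM (-4.38) or 1 uM (-5.07). For Mgmt the single untreated array therefore stands apart from both others.

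For the ERK cascade, the arrays measured transcripts and not kinase activity. Of 23 cascade kinases and receptors, 1 was at least 2-fold apart at 1 uM. That gene was Rasa1, a Ras GTPase-activating protein, 2.54-fold higher. Mapk3 differed by -0.51 on the log2 scale and Pdgfrb by -0.85. Of 20 ERK feedback and target genes, Etv1 was 2.12-fold higher and Hbegf 2.05-fold lower. Dusp6 differed by 0.11, Spry1 by 0.84 and Fosl1 by -0.26. The list median was 0.16, at percentile 99.5, and was 0.36 after quantile normalization. Immediate early genes, ranked as a separate list, went the other way, with a median of -0.95.

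Genes that respond to metals and oxidants went both ways at 1 uM. Of 37 NRF2 and glutathione genes, 2 were at least 2-fold higher and 3 lower. The cystine transporter gene Slc7a11 was 4.08-fold higher (other probes from 1.20 to 2.31 on the log2 scale) and Gsta1 2.06-fold, whereas Osgin1 was 3.32-fold lower, Gstm1 at least 2.37-fold and Gstm2 2.17-fold. The Gsta and Gstm families hold near-identical copies, so these assignments are uncertain. Of 13 metal response genes, metallothionein Mt1 was at least 2.51-fold lower on its brighter probe, and another Mt1 probe lay within 1.5-fold. Slc30a1 was 2.30-fold lower, with another probe within 1.5-fold, and Cp was 2.09-fold higher. Slc20a1, a phosphate transporter gene, was 2.57-fold higher. Among 19 lipoic acid and 2-oxoacid dehydrogenase genes, Bckdha was 3.11-fold lower and 0 were at least 2-fold higher.

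The second comparison asked the same of the 0.01 uM dose. Few genes differed by 2-fold, and 0 of the members of the 36 lists did so. Rbpms2, an RNA-binding protein gene, was 2.95-fold lower and Preb, a regulator of secretory transport, 2.22-fold lower. Rpe65 and Ak8 were at least 3.03-fold and 2.98-fold lower. Rplp1-ps1, a ribosomal pseudogene with near-identical copies, was 2.14-fold lower and is uncertain. Preb and Rplp1-ps1 differed between the 2 doses by only -0.13 and -0.16 on the log2 scale, and Rpe65 and Ak8 were not well above background on either treated array. For these 4 genes it is the single untreated array that stands apart from both others. These 5 were all the genes that met the naming rule, and 0 higher genes met it. Of 11915 genes compared, 31 were at least 2-fold higher and 20 lower, and 35 of the 51 were bounds with 1 array not well above background or saturated. The share of higher genes was 60.8%. It was 72.3% after quantile normalization, 48.3% after scaling to the 75th percentile of detected probes and 93.9% after spike-in scaling. With both arrays required to be well above background, 8 higher and 8 lower genes were counted.

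The highest list median at 0.01 uM was that of 44 cytosolic ribosomal protein genes, 0.44, which was 0.028 after quantile normalization and 0.14 after loess scaling. Of these genes, 34 were saturated on at least 1 array, and the median over the other 10 was 0.18. With genes saturated on both arrays set to 0, the list median was 0, which that rule fixed in advance. Immediate early genes had a median of 0.28, with 0 of 20 members past 2-fold and 2 at least 1.5-fold higher, and the median was 0.083 after quantile normalization. The interferon list had a median of -0.11 over 29 members at this dose, which was 0.003 with normexp and 0.24 after spike-in scaling. Mapk3 differed by 0.13, and Dusp6 and Phlda1 by 0.21 and 0.41.

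Between the 2 doses, 627 genes were at least 2-fold higher at 1 uM and 778 lower, of 12059 compared. The median difference of genes detected on both arrays was -0.12. The share of higher genes was 44.6%. It was 57.9% after loess scaling, 57.6% with the 75th percentile of detected probes and 79.2% after spike-in scaling. Saa3 was at least 42.6-fold higher at 1 uM than at 0.01 uM, Akr1c18 10.6-fold, Usp18 at least 8.74-fold, Oasl2 at least 8.64-fold and Slfn2 7.83-fold. Thy1 was at least 74.3-fold lower, Islr 29.3-fold, Ccn5 28.5-fold, Fosb 25.8-fold, Sema3g 25.3-fold and Mfap5 at least 24.3-fold. Adat1 led again, with the same single spot.

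The 2 doses' differences against the shared untreated array were compared across 10575 genes detected on all 3 arrays. Pearson's r was -0.20, Spearman's rho -0.24 and the covariance -0.023. Without a filter on dim probes r turned to 0.28. Unchanged arrays sharing 1 control, simulated with the spot noise, gave an r of 0.49 and a covariance of 0.0034. Spot noise was alike on the 3 arrays, whereas the measured differences had an SD of 0.61 at 1 uM and 0.20 at 0.01 uM. The simulated r is therefore no reference for the size of the measured r. Genes are not independent replicates, and the single control could not be split. Of 11892 genes in both comparisons, 3 were at least 2-fold higher at both doses (0.44 for independent lists) and 11 lower at both (1.02 for independent lists). Independent lists share no array, so those numbers are no reference. These are by definition the 14 genes for which the untreated array stood 2-fold away from both others. A response common to both doses and a departure of that single array cannot be told apart in them. On the 1 uM array, 952 genes stood at least 2-fold away from both other arrays in the same direction, against 23 on the 0.01 uM array and 14 on the untreated array. The variance of each array's own departure, estimated as if the departures were unrelated, was 0.36, 0.062 and -0.023 in the same order. For the untreated array this estimate is the same quantity as the covariance above, and not a separate result. A variance cannot be negative, so the departures were not unrelated and the 3 values are rough descriptions only.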

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

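The scaling test of the interferon pattern and both tests of the ribosomal pattern were written before their values were seen, and the tests on blood cells, single spots and another cell stock were chosen afterwards. Rbpms2 lay on opposite sides of the untreated array at the 2 doses, at 1.07 for 1 uM and -1.56 for 0.01 uM on the log2 scale, which puts the 1 uM array 2.63 above the 0.01 uM array. With 1 array per dose this difference was not tested.

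Interferon response genes were higher on the 1 uM array, with a median of 1.33. Array scaling is argued against, because the lowest median over the scaling and background alternatives was 1.13. For RNA of blood or immune cells, 0 of 8 abundant leukocyte transcripts were gained or at least 2-fold higher on that array. Ptprc, Tyrobp and Laptm5 were not well above background there. That argues against such RNA for these transcripts alone. Those 8 were picked after the values were seen. Of all 22 listed markers 1 was gained, the macrophage gene Aif1, at -2.29 on that array and -3.26 on the untreated array. The leukocyte gene Cd53 stood at -2.92 on the 1 uM and -4.71 on the untreated array, well above background on neither. Cd74, Rnase2a, Plcg2 and Ccl3, which immune cells also express, were higher at 1 uM, with signals of 0.38, 0.58, 0.48 and -0.53 there. Ptprc (-5.05), Tyrobp (-5.05) and Laptm5 (-5.06) had signals not well above background. Signals of different probes do not compare as transcript amounts, so the gap between these levels decides nothing. RNA of immune cells in that culture therefore stays open. A response to Cr(VI), and an infection or another event in the cells of that array, in 1 flask or in all if their RNA was pooled, stay open and were not tested.

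The 1 uM array stood apart from the other 2. Noise of single spots is argued against for genes with 2 detected probes, whose log2 differences correlated across 3237 genes with r = 0.74. Of 162 such genes past 2-fold, the second probe had the same sign in 156 and was also past 2-fold in 96. Genes with 1 probe and genes given as bounds are not covered. Another stock of cells on that array cannot be told apart from the dose. The largest chromosome median was 0.097 away from that of all genes, but a stock of the same karyotype would shift no chromosome. The dose itself, the culture, RNA quality and labelling all coincide with this 1 array.

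Ribosomal protein genes were higher on the 0.01 uM array, with a median of 0.44, which was 0.028 after quantile normalization. After loess scaling the median was 0.14, above the bound of 0.1 set beforehand, yet 34 of the 44 genes were saturated on at least 1 array, so this value decides nothing about a trend with brightness. Without the saturated genes the median was 0.18, between the bounds set for saturation as the cause. Of the 44 genes, 33 were saturated on the untreated and 32 on the 0.01 uM array. Between saturated spots, the log2 difference follows the arrays' scaling constants (9.45 and 9.01) rather than transcript levels. The 0.44 therefore rests largely on saturation. Random lists matched on the brightness of all 44 genes had a median of 0.19. For the 10 unsaturated genes, a trend with brightness and the dose cannot be told apart.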

How the results depend on the processing

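No paired analysis was possible because each group had 1 array. The authors' values have the scale and centring of the main setting, so their equal counts are no separate check. Of the 693 higher and 605 lower genes at 1 uM, quantile normalization shared 644 and 557, loess 686 and 518 and normexp 290 and 428. The median of detected probes moves all genes up by 1 constant, which kept every higher gene by construction and 542 lower ones. Causes of the shifts below were not tested unless stated. Of 114 genes named past 2-fold at 1 uM, 96 stayed past 2-fold in the same direction with normexp, 109 with quantile or loess and 85 with spike-in scaling. The largest-difference genes were picked to pass normexp and quantile, which fixes part of these counts. Signal over background limits the counts: without a filter dim probes enter by construction.

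With normexp, 1 uM against untreated gave 740 genes (290 higher), 0.01 uM against untreated 16 (10 higher, 6 lower) and 1 uM against 0.01 uM 898 (375 higher). Genes 2-fold away from both other arrays were then 4 for untreated, 9 for 0.01 uM and 612 for 1 uM, and the interferon median at 0.01 uM was 0.0026 in place of -0.11. With no filter the counts were 2924 (1758 higher, 1166 lower), 984 (721 and 263) and 3108 (1534 and 1574). Genes away from both others were 229, 507 and 1837, the r between doses was 0.28 in place of -0.20, and the medians were 0.15 for epithelial-mesenchymal genes at 0.01 uM (main -0.019) and 0.15 for bone and cartilage genes at 1 uM (main -1.23). With both arrays above background, fewer genes were compared: 0.01 uM against untreated gave 16 (8 higher, 8 lower), and 5 genes stood apart on the untreated and 5 on the 0.01 uM array. Quantile normalization gave 13 lower genes at 0.01 uM.

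A 3-fold threshold gave 368 genes (167 higher, 201 lower), 11 (9 and 2) and 426 (172 and 254) by its construction. Spike-in scaling, added after seeing the data, moved the median of all genes to 0.69 at 1 uM and 0.41 at 0.01 uM, by 1 constant per array. It gave 3685 genes (3520 higher, 165 lower) at 1 uM, 82 (77 and 5) at 0.01 uM, and 1376 higher and 361 lower between doses, with 29, 14 and 1498 genes away from both others for untreated, 0.01 uM and 1 uM. Among lists past percentile 1 or 99, medians changed sign with it at 1 uM for collagens (0.19), smooth muscle genes (0.24), hypoxia genes (0.37) and IGF and Wnt genes (0.29), and at 0.01 uM for epithelial-mesenchymal genes (0.34), interferon genes (0.24) and cholesterol genes (0.34). At 1 uM the negative medians of other lists nearer 0 than this constant turned too, such as YAP and SRF targets (0.44).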

Other observations

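Further gene groups were listed after their members' values had been seen, so their ranks describe these arrays and are not independent evidence. Ribosome biogenesis genes, which process ribosomal RNA and assemble ribosomes in the nucleolus, had a median of 0.61 at 1 uM. Of 49 measured, 17 were at least 2-fold higher and 0 lower. The RNA polymerase I subunit gene Polr1b was 2.02 higher on the log2 scale, Heatr1 1.67, Bysl 1.39 and Nop56 1.14. Their median at 0.01 uM was -0.05. BMP signalling and target genes were lower at 1 uM, with a median of -1.02 (-0.60 without a filter on dim probes), and 10 of 19 measured were at least 2-fold lower. Id2 stood at -2.95, Hes1 at -2.69, Bmp4 at -2.23, Id3 at -2.16 and Smad6 at -1.82.

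Complement genes had a median of -1.03 at 1 uM, with 7 of 13 at least 2-fold lower and 1 higher. The median was -0.62 with the mean of probes, and 0.14 without a filter on dim probes. C4b stood at -2.70, C1s1 at -1.40 and C1ra at -1.03. Replication-dependent histone genes, which have near-identical copies and are uncertain one by one, had 8 of 25 measured at least 2-fold lower and 0 higher, although the DNA replication list had a median of 0.37.

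The 6 unsaturated spike-in probes, each on 32 spots, were lower relative to the 75th percentile on both treated arrays. Their mean difference was -0.74 at 1 uM (SD 0.13 over probes) and -0.36 at 0.01 uM (SD 0.12). The amounts of spike-in and RNA per labelling are not known, so these values say nothing about the cells. The Adat1 spot had 45 saturated pixels of 56 on the 1 uM array and 0 on the other arrays, while the median signal of its 19 neighbouring spots was 28.2 on the 1 uM array and 22.1 on the untreated array. Xist, the X-inactivation RNA, had a log2 signal of 4.14, 4.20 and 3.67 on the untreated, 0.01 uM and 1 uM arrays of this cell line, and 0 of 7 Y-linked probes were well above background on any of them.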
